A study of Mus musculus with 44 samples.

How the data were processed

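The series measured gene expression by 3′ tag RNA sequencing in cells sorted from mouse lungs. Per the labels and the series description, young recipient mice were given bone marrow from young or aged donors and then received bleomycin, a drug that injures the lung and leads to fibrosis, through the trachea at 1 U/kg. Sorting gave 5 labelled populations, named Monocytes, MoAM, AM, CD25pos and CD25neg, at D7 after bleomycin, and MoAM and AM again at D14. The labels do not spell out MoAM and AM, which this field commonly uses for monocyte-derived alveolar macrophages and for alveolar macrophages. CD25 is the alpha chain of the interleukin-2 receptor, which regulatory T cells carry at high level. Per the labels' protocols, 30000 to 80000 cells were sorted for each library, RNA was purified with an RNeasy Micro kit, and libraries were made with the forward QuantSeq 3′ kit and its second strand module carrying unique molecular identifiers.

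The values used were the counts per gene deposited by the authors, in a table with 1 column per library and 1 line per gene symbol. Per the submitters' processing notes, reads were handled with Picard, Trim Galore 0.6.6, FastQC, STAR 2.7.9a, featureCounts and edgeR 3.36.0. The notes name the builds mm10 and GRCm39 without saying which served for what, so no coordinates are given. Whether the molecular identifiers were collapsed, how reads with several matches were treated and whether strand was used in counting are not given in the sources used here. Genes with near-identical copies or pseudogenes, among them ribosomal protein, globin and MHC class II genes, are therefore uncertain one by one. A second deposited table, in CPM, was the count table times 1 factor per library and was not used. All 44 columns were matched to samples by name alone, with 0 columns left out and 0 lines naming no gene. The table held 19910 genes, of which 1203 had no count in any library, and 97.4% of the symbols matched GENCODE M21, used for names and gene types only. Of the 19400 matched symbols 19313 were protein coding (99.6%). No pair of libraries within a group was identical (0 pairs), and the chi-squared per degree of freedom between such pairs ranged from 2.069 to 71.18.

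Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by TMM, and each comparison used the robust quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, called at 0.05. Every adjusted p given for a gene comes from this edgeR test unless another tool is named. The MoAM libraries, the AM libraries, and the CD25pos and CD25neg libraries formed 1 fit each, with 1 coefficient per group, and the monocyte libraries formed their own. AM with MoAM at D7 and MoAM with monocytes at D7 were fitted for the comparisons between populations, as the mean over both marrow ages. No aged D14 against D7 test was made in AM, since the 3 libraries labelled AM D14 aged carry another run number in their column names than all the others. If the names hold for the values, which lineage genes leave in doubt, run and marrow age cannot be told apart in that group. CPM are counts scaled to a common library total: means for named genes are TMM scaled, CPM for lineage genes per library are counts over the library total, and errors are SDs unless a standard error is named. A fold against a group with no count is a lower bound, computed against 3 counts over that group. Such floors cover counting error only.

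Gene lists, 40 in all with 13 of cell type markers, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. An estimated correlation between genes and the fry test were alternatives. Of the camera calls, those that held with an estimated correlation numbered 5 in MoAM young D14 against D7, 4 in MoAM aged D14 against D7 and 1 in AM against MoAM; the list tests were not rerun with libraries left out. For lists of population genes, the 100 genes with the smallest p higher in AM and the 100 lower in AM were taken from the young D7 libraries and tested in MoAM D14.

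For each aged against young comparison, up to 10 genes higher and 10 lower were named, those with the largest absolute log2 fold change among genes past the test, with a mean of 10 CPM or more in a group and with no overlap between the libraries of the groups. Every library of the higher group therefore lies above every library of the other for these genes. Predicted genes, pseudogenes, unnamed identifiers and antigen receptor segments were counted and not named. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were named as not passing. Up to 10 list members with the smallest p past the test and a fixed panel, 18 genes for macrophages and monocytes and 15 for CD25pos and CD25neg, were added whatever their result. Other comparisons named up to 5 genes in each direction and the panel. The text gives a selection of these genes in full and the rest as counts.

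The alternatives were RLE size factors, no filter, a filter of 10 CPM, the replicate number as a block, DESeq2 1.42.0, limma voom with quality weights, all 44 libraries in one fit, only the groups compared, monocytes fitted with MoAM D7, and each library left out in turn. The whole procedure was tested on simulated counts, drawn from 1 mean per gene over all libraries of a fit and from their library sizes. The spread was set by expression level alone, so no simulated group held a library of another lineage. False calls numbered 1 to 9 per comparison, among them 4 of 57 calls for CD25pos and 5 of 87 for AM D14 in aged against young. Of 100 genes changed 4-fold, it recovered 70 for monocytes, 73 for MoAM D7, 71 for MoAM D14, 83 for AM D7, 70 for AM D14, 51 for CD25pos and 38 for CD25neg in aged against young. Of 100 genes changed 2-fold it recovered 10, 20, 12, 14, 12, 2 and 3 in the same order. At 4-fold it recovered 87 for MoAM young by day, 81 for MoAM aged by day, 82 for AM young by day, 79 for the CD25 gate, 94 for AM against MoAM and 97 for MoAM against monocytes. The interactions recovered 45 of 100 for MoAM age by day, 42 for age by macrophage population and 7 for age by CD25 gate. In 40 simulated lists the 1 shifted list was called and 0 others were. Changed genes were drawn from the more highly expressed ones only. Simulated genes varied independently, so the simulated lists say nothing about false calls where the genes of a list vary together.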

Results

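The data comprised 44 libraries in 14 groups, each set by labelled population, time point and age of the donor marrow. At D7 there were 2 young and 3 aged monocyte libraries, 4 and 4 for MoAM, 3 and 4 for AM, 3 and 3 for CD25pos, and 4 and 2 for CD25neg. At D14 there were 3 and 3 for MoAM and 3 and 3 for AM. Total counts per library ran from 126283 to 9921734 with a median of 1780800, and 8042 to 15639 genes had a count. In young groups, totals were 625141 to 2192505 for monocytes, 327542 to 2569523 for MoAM D7, 1004846 to 3626609 for MoAM D14, 234968 to 3140626 for AM D7, 485090 to 9921734 for AM D14, 2787165 to 5651589 for CD25pos and 783477 to 2381358 for CD25neg. In aged groups they were, in that order, 126283 to 5698102, 365949 to 3114658, 731787 to 4861369, 2005964 to 5744232, 1137441 to 3453587, 233754 to 1258235 and 658368 to 2259211. The labels do not say whether the libraries of a group come from separate animals, so every p-value measures a spread between libraries that can be technical. The study asked whether old marrow changes the transcriptome of lung immune cells after injury.

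Genes that mark cell lineages went against the labels of the libraries. Cd3e, a chain of the T cell receptor complex, reached 313, 251 and 126 CPM in the libraries labelled MoAM D14 young and 209, 87.0 and 88.0 CPM in those labelled MoAM D14 aged. Cd3e lay between 0 and 29.1 CPM in the 12 libraries labelled CD25pos or CD25neg. Foxp3, the transcription factor of regulatory T cells, was 96.7, 114 and 112 CPM in AM D7 aged 1, 2 and 3 and 1.74 CPM in aged 4, and at most 2.87 CPM in any library labelled CD25pos. Lyz2, the lysozyme gene of myeloid cells, lay between 19500 and 29660 CPM in the libraries labelled CD25pos and between 579 and 3140 CPM in those labelled MoAM D14. Siglecf, a surface lectin of resident alveolar macrophages and eosinophils, was 73.6 to 166 CPM in libraries labelled monocytes and 0 to 32.96 CPM in libraries labelled AM. Car4, a carbonic anhydrase of resident alveolar macrophages, was 556 to 1081 CPM in libraries labelled monocytes against 53.4 to 224.5 CPM in those labelled AM. Ly6c2, a surface protein of classical monocytes, was 7.30 to 47.5 CPM in libraries labelled monocytes and 603 and 680 CPM in CD25neg aged 1 and 2, with 88.07 to 1845 CPM in CD25neg young.

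The same held for the fixed lists of lineage genes, taken as mean log2(CPM + 1). Of the 12 libraries highest in the T cell list, 6 were labelled MoAM D14, 3 AM D7 young and 3 AM D7 aged, and 0 of 12 were labelled CD25pos or CD25neg. Of the 13 libraries highest in the resident alveolar macrophage list, 5 were labelled monocytes and 8 MoAM D7, and 0 of 13 were labelled AM. All 5 libraries highest in the classical monocyte list were labelled CD25neg, 3 young and 2 aged. These are descriptions of single libraries, made without a test. The groups in every comparison are therefore named by their labels, as the libraries labelled so. A difference between libraries labelled aged and young cannot be read as an effect of marrow age. Nor can one between labelled days or populations be read as an effect of time or of cell type.

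**Figure D1:**
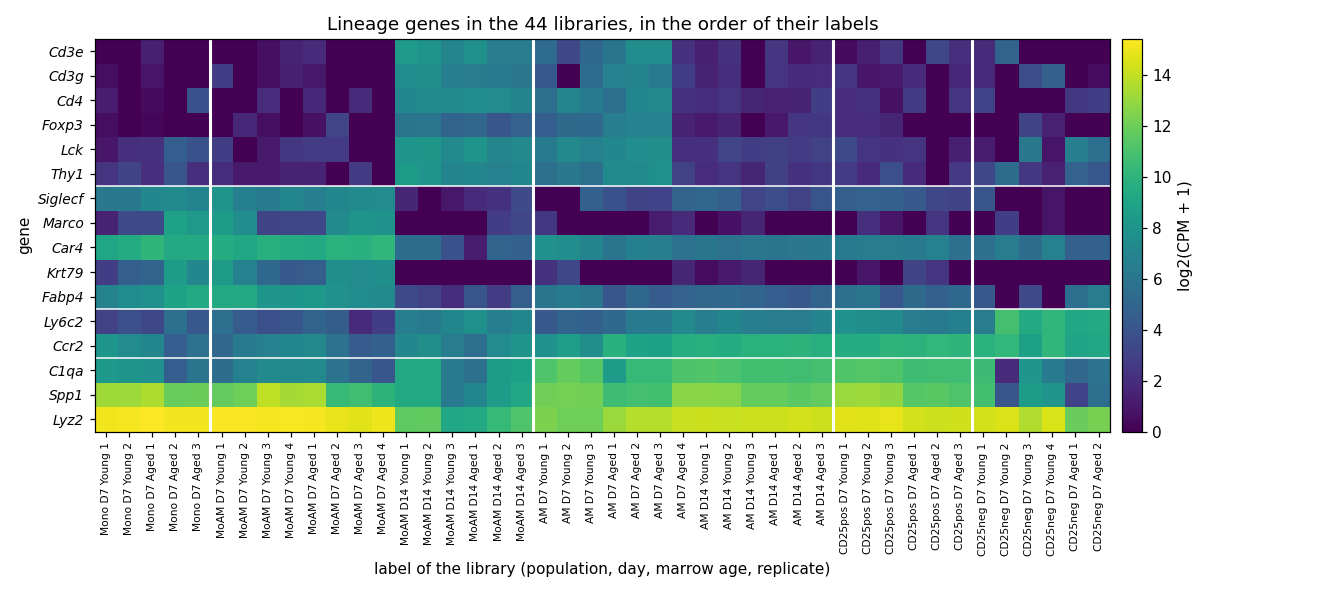
Log2(CPM + 1) of 16 lineage genes (vertical axis) in each of the 44 libraries (horizontal axis, by labelled group), with the colour scale in the same unit. T cell genes are high in the libraries labelled MoAM D14 and in most labelled AM D7, and low in the 12 labelled CD25pos or CD25neg.

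**Figure D2:**
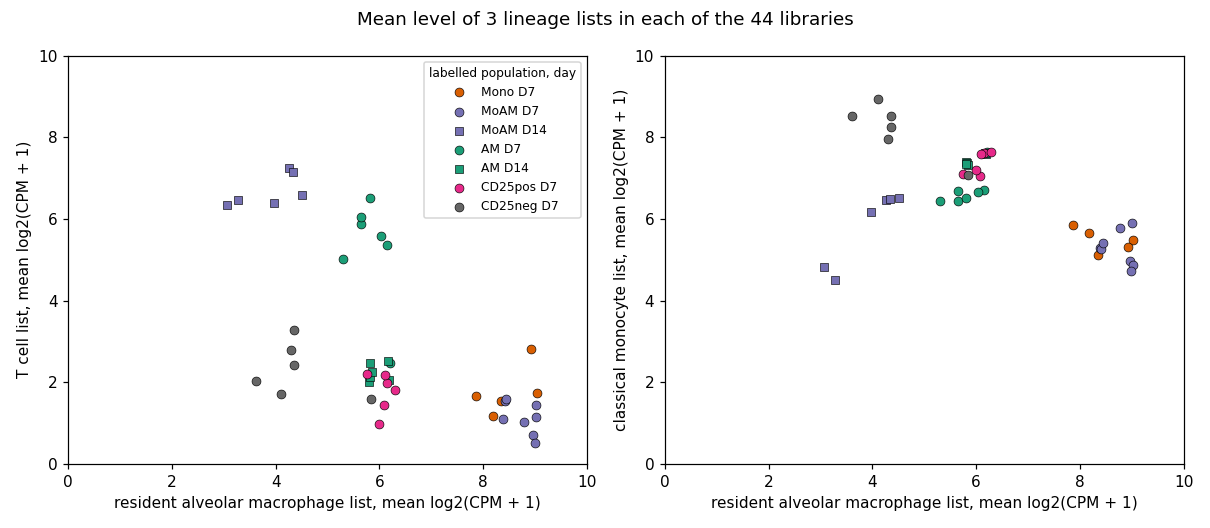
Mean log2(CPM + 1) of the T cell list and of the classical monocyte list (vertical axes) against that of the resident alveolar macrophage list (horizontal axes), 1 point per library, coloured by labelled population. The 13 libraries highest in the alveolar macrophage list are those labelled monocytes and MoAM D7.

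In the libraries labelled monocytes, 3 aged were compared with 2 young. The 5 genes with the smallest unadjusted p did not pass the test. Among them were Wfdc17, a secreted inhibitor made by macrophages, at 515 ± 139 CPM against 1230 ± 38.2 CPM, and Cd2, an adhesion molecule of T and NK cells, at 133 ± 71.0 CPM against 25.01 ± 9.66 CPM. Spp1, which codes for osteopontin, had 6430 ± 4192 CPM against 9540 ± 100 CPM and Marco, a scavenger receptor of resident alveolar macrophages, 272 ± 237 CPM against 5.94 ± 5.82 CPM. By edgeR 0 of 7250 genes were called, with 208 at an unadjusted p under 0.05, a smallest adjusted p of 0.637, and 0 calls by DESeq2 and by limma voom. The resident alveolar macrophage list was higher in aged over 30 members (camera adjusted p = 2.32e-05, adjusted p = 0.712 with an estimated correlation), with 0 members called and 2 higher when adjusted over the list alone. The MHC class II list, whose proteins present antigen, was lower over 8 members (camera adjusted p = 0.0128, adjusted p = 0.712 with an estimated correlation), with 0 members called over all genes and 2 lower when adjusted over the list alone. Camera called 5 lists in all, 3 higher and 2 lower, and 0 with an estimated correlation. Markers of endothelium were higher as a list over 6 members (camera adjusted p = 0.00622, adjusted p = 0.712 with an estimated correlation). The interferon response list was lower over 22 (camera adjusted p = 0.00753, adjusted p = 0.712 with an estimated correlation) and the lipid handling list higher over 22 (camera adjusted p = 0.034, adjusted p = 0.712 with an estimated correlation). In these 3 lists 0 members were called, and adjusted over the list alone 1 lipid handling gene was higher. Without aged 1 the count of called genes was 140 and without young 2 it was 3.

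The libraries labelled MoAM D7 were 4 aged and 4 young. The gene with the smallest p was Il18r1, a receptor chain for interleukin-18, with 0.234 ± 0.469 CPM in aged and 6.16 ± 3.08 CPM in young. Bach2, a repressor that keeps lymphocytes in a resting state, had 25.2 ± 8.45 CPM against 71.0 ± 47.2 CPM, and Fabp4, a fatty acid carrier of alveolar macrophages, 233 ± 78.1 CPM against 505.5 ± 237 CPM. Neither these nor any of the 18 panel genes passed. By edgeR 0 of 10424 genes were called, with 307 at an unadjusted p under 0.05 and a smallest adjusted p of 0.66, against 0 by DESeq2 and 9 by limma voom. Camera called 12 lists, 1 higher and 11 lower in aged, and 0 of them with an estimated correlation. The naive and central memory T cell list was lower over 20 members (camera adjusted p = 0.00235, adjusted p = 0.444 with an estimated correlation), with 0 members called and 4 lower when adjusted over the list alone. The interferon response list of 37 members was lower (camera adjusted p = 0.0126, adjusted p = 0.8 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. The 1 list higher was that of immediate early and dissociation stress genes, which respond to the handling of cells, over 27 members (camera adjusted p = 0.0299, adjusted p = 0.8 with an estimated correlation), with 0 members called and 1 higher and 1 lower adjusted over the list alone. Markers of other cell types were lower as lists: fibroblast over 11 members (camera adjusted p = 0.0126), alveolar epithelium over 13 (0.022), endothelium over 11 and B cell over 13 (0.027 for each) and dendritic cell over 14 (0.0497). Each of these had adjusted p = 0.8 with an estimated correlation, 0 members called and 0 adjusted over the list alone.

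In the libraries labelled MoAM D14, 3 aged and 3 young, Sqle was lower in aged. Sqle, which codes for squalene epoxidase of sterol synthesis, had 1.24 ± 1.95 CPM in aged against 22.01 ± 3.23 CPM in young (log2 fold change -3.62, standard error 0.60, edgeR adjusted p = 0.037). It was the 1 gene called of 10424, with 696 at an unadjusted p under 0.05. Angptl4, a secreted inhibitor of lipoprotein lipase, had 0.611 ± 1.06 CPM against 8.58 ± 2.03 CPM and did not pass (edgeR adjusted p = 0.149). Siglecf had 5.13 ± 3.72 CPM against 0.927 ± 0.898 CPM (edgeR adjusted p = 0.314), and no other panel gene had a smaller adjusted p. The list of genes encoded by mitochondrial DNA was higher over 8 members (camera adjusted p = 0.00401, adjusted p = 0.934 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. The Sqle call ended without young 1 and without aged 3, with a highest adjusted p of 0.114 by edgeR. It also ended with the replicate number as a block, when only these groups were fitted, and by limma voom, whose 2 calls shared 0 with edgeR. The count of calls was 80 without young 3, 10 without aged 1, 6 without aged 2 and 2 without young 2, 27 by DESeq2 and 2 by limma voom. Young 3 and aged 1 stood apart in lineage lists, taken as mean log2(CPM + 1): 4.81 and 4.51 in the classical monocyte list against 6.18 to 6.52 in the other 4, and 3.06 and 3.27 in the resident alveolar macrophage list against 3.97 to 4.51.

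The libraries labelled AM D7 were 4 aged and 3 young. Ribosomal protein genes were higher in aged in 42 of 66 and lower in 0 (camera adjusted p = 3.15e-10, adjusted p = 0.835 with an estimated correlation), with 47 higher and 4 lower adjusted over the list alone. Among them were Rpl37 at 2458 ± 336 CPM against 387 ± 76.3 CPM (log2 fold change 2.66, standard error 0.23, edgeR adjusted p = 3e-06) and Rpl30 at 1494 ± 449 CPM against 248 ± 30.1 CPM. Hbb-bs, an adult beta globin of red cells, was at 331 ± 77.3 CPM against 4.62 ± 4.89 CPM (log2 fold change 5.88, standard error 0.52, edgeR adjusted p = 3e-06). H2-Eb1 and H2-Aa, chains of MHC class II, were at 1845 ± 352 CPM against 387 ± 79.7 CPM and 3231 ± 703 CPM against 911.5 ± 113 CPM. Cxcl2, a chemokine that draws neutrophils, was at 4801 ± 1437 CPM against 893 ± 53.9 CPM, and S100a4, a calcium-binding protein of motile cells, at 1713 ± 77.1 CPM against 555 ± 22.8 CPM. Ly6c2 was at 95.4 ± 56.2 CPM against 20.8 ± 4.00 CPM (log2 fold change 2.19, standard error 0.44, edgeR adjusted p = 0.0038), a call that ended when only these groups were fitted. Zfp598, a ubiquitin ligase that senses stalled ribosomes, was at least 46-fold higher at 26.7 ± 7.81 CPM, and Adi1, an enzyme of methionine salvage, at least 41.7-fold higher at 24.2 ± 18.8 CPM. Lower in aged were Thbs1, the matrix glycoprotein thrombospondin-1, at 119 ± 36.9 CPM against 624.5 ± 56.9 CPM (log2 fold change -2.40, standard error 0.26, edgeR adjusted p = 2.81e-05), Efnb1, an ephrin ligand, at 2.04 ± 1.94 CPM against 45.3 ± 44.3 CPM, and Cacna1c, a calcium channel subunit, at 2.46 ± 2.25 CPM against 38.7 ± 21.6 CPM.

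Camera called 11 lists in the same libraries labelled AM D7, 8 higher and 3 lower in aged, and 0 with an estimated correlation. Of 45 oxidative phosphorylation genes, 22 were higher and 0 lower (camera adjusted p = 1.62e-08, adjusted p = 0.835 with an estimated correlation), and 33 adjusted over the list alone. Of 8 genes encoded by mitochondrial DNA, 6 were higher (camera adjusted p = 7.45e-05, adjusted p = 0.835 with an estimated correlation), and 7 adjusted over the list alone. Mitochondrial genes took 0.796 to 1.02% of the counts in the young libraries and 2.34 to 3.02% in the aged. This is a shift of whole libraries, and whether it reflects their quality or content was not tested. Of 40 cell cycle genes 7 were higher (camera adjusted p = 0.00253, adjusted p = 0.835 with an estimated correlation), and 9 adjusted over the list alone. Markers of other cell types moved in the same comparison: 5 of 8 erythroid and platelet genes were higher (camera adjusted p = 0.00675, adjusted p = 0.835 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone) and 3 of 12 endothelial genes were lower (camera adjusted p = 0.00453, adjusted p = 0.835 with an estimated correlation; 5 lower adjusted over the list alone). Of 10 NK cell genes 4 were higher (camera adjusted p = 0.00282, adjusted p = 0.835 with an estimated correlation), and 6 adjusted over the list alone. Of 15 macrophage markers 5 were higher, and 8 adjusted over the list alone (camera adjusted p = 0.0466, adjusted p = 0.835 with an estimated correlation). Of 18 neutrophil genes 2 were lower, and 2 adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.835 with an estimated correlation). Cd3e was 63.3, 185, 189 and 3.66 CPM in aged 1 to 4 and 41.04, 8.51 and 34.7 CPM in young 1 to 3. EdgeR called 1165 of 11682 genes, 834 higher and 331 lower, and DESeq2 called 2198, limma voom 823 and a fit of only these groups 216. Of the 34 named genes called, 22 stayed called without each library in turn. The panel genes Fn1, Mmp12 and Il1b were among the 12 that did not: Fn1, fibronectin, and Mmp12, a macrophage elastase, lost their calls without any 1 of young 1, 2 and 3 or aged 4, and Il1b, the cytokine interleukin-1 beta, without young 2, with highest edgeR adjusted p of 0.0972, 0.186 and 0.0705. These 3 calls also ended with the replicate number as a block, by limma voom, in the fit of all 44 libraries and when only these groups were fitted, and that of Mmp12 with no filter.

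In the libraries labelled AM D14, 3 aged and 3 young, no gene passed the test. Klf2, a transcription factor of quiescence and trafficking, had 165 ± 23.6 CPM in aged against 392 ± 190 CPM in young, and Retnla, a secreted protein of alternatively activated macrophages, 18.95 ± 1.56 CPM against 68.2 ± 29.5 CPM. Spp1 had 3414 ± 360 CPM against 5798 ± 1931 CPM and Mmp12 505 ± 18.3 CPM against 1492 ± 861 CPM. EdgeR called 0 of 11682 genes, with 104 at an unadjusted p under 0.05, against 0 by DESeq2, 1277 by limma voom, and 84 when only these groups were fitted. Without young 3 the count was 3. Camera called 10 lists and 0 with an estimated correlation, among them the ribosomal protein list, higher over 66 members (camera adjusted p = 5.61e-06, adjusted p = 0.904 with an estimated correlation), and the interferon response list, lower over 38 members (camera adjusted p = 0.00267, adjusted p = 0.904 with an estimated correlation). The endothelial list of 12 members was higher (camera adjusted p = 2.88e-08, adjusted p = 0.362 with an estimated correlation). So were the fibroblast list of 13 and the erythroid and platelet list of 8 (camera adjusted p = 0.0355 for each, adjusted p = 0.904 with an estimated correlation for each), while the B cell list of 13 was lower (camera adjusted p = 0.00931, adjusted p = 0.904 with an estimated correlation). In each of these lists 0 members were called over all genes and 0 adjusted over the list alone. The aged libraries of this comparison carry another run number in their column names than the young ones. If the names hold for the values, which lineage genes leave in doubt, run and label cannot be told apart.

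In the libraries labelled CD25pos, 3 aged and 3 young, Kcnmb2 and Stpg3 were higher in aged. Kcnmb2, an auxiliary subunit of a calcium-activated potassium channel, had 804 ± 183 CPM against 90.2 ± 18.4 CPM (log2 fold change 3.16, standard error 0.32, edgeR adjusted p = 0.000466). Stpg3 had 158 ± 23.6 CPM against 18.65 ± 2.46 CPM (log2 fold change 3.08, standard error 0.42, edgeR adjusted p = 0.0101). Klf2 had 129 ± 32.5 CPM against 527 ± 118 CPM and Mpeg1, a pore-forming protein of macrophages, 536 ± 69.1 CPM against 1229 ± 106 CPM, and neither passed (edgeR adjusted p of 0.141 and 0.268). Of the 15 T cell panel genes 11 were tested and none passed; Foxp3 and Il17a were among those with too few counts. EdgeR called 2 of 10552 genes, with 262 at an unadjusted p under 0.05. DESeq2 called 11, of which 1 was shared with edgeR. Limma voom called 545, a fit of only these groups 695 and the fit of all 44 libraries 1. In the fit of all 44 libraries neither Kcnmb2 nor Stpg3 was called. Stpg3 lost its call without each of the 6 libraries in turn, young 1, 2 and 3 and aged 1, 2 and 3, which left 1 call each time and a highest edgeR adjusted p of 0.2. Camera called 13 lists, 5 higher and 8 lower, and 0 with an estimated correlation. The ribosomal protein list was higher over 66 members (camera adjusted p = 4.2e-14, adjusted p = 0.353 with an estimated correlation), the cell cycle list higher over 40 (camera adjusted p = 2.09e-05, adjusted p = 0.61 with an estimated correlation) and the lipid handling list lower over 22 (camera adjusted p = 0.00121, adjusted p = 0.249 with an estimated correlation). Markers of other cell types were lower as lists: fibroblast over 9 members (camera adjusted p = 0.000495, adjusted p = 0.249 with an estimated correlation), endothelium over 11 (camera adjusted p = 0.00203, adjusted p = 0.249 with an estimated correlation) and plasma cell over 5 (camera adjusted p = 0.0267, adjusted p = 0.271 with an estimated correlation). In these lists 0 members were called over all genes and 0 adjusted over the list alone.

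Among the libraries labelled CD25neg, 2 aged and 4 young, 6 of 7 genes of the respiratory chain encoded by mitochondrial DNA were lower in aged (camera adjusted p = 1.31e-11, adjusted p = 0.0963 with an estimated correlation), and 6 adjusted over the list alone. Of these, mt-Nd4 lost its call without aged 1 and mt-Co1 without aged 1 and without aged 2, with highest edgeR adjusted p of 0.0788 and 0.288. The complex I subunits mt-Nd2 and mt-Nd1 had 676 ± 98.7 CPM against 6042 ± 1783 CPM and 2144 ± 364 CPM against 10090 ± 1650 CPM (log2 fold changes -3.16 and -2.23, standard errors 0.33 and 0.24, edgeR adjusted p = 0.000417 for each). Cytochrome b, mt-Cytb, had 988 ± 303 CPM against 5749 ± 1123 CPM. Mitochondrial genes took 0.666 and 0.886% of the counts in aged 1 and 2 and 3.11 to 4.50% in the young libraries. Whether this shift of whole libraries reflects their quality or content was not tested. Lyz2 was at 3533 ± 737 CPM against 21280 ± 6059 CPM (log2 fold change -2.59, standard error 0.29, edgeR adjusted p = 0.000417). Trem2, a lipid-sensing receptor of macrophages, was at 6.24 ± 5.11 CPM against 78.3 ± 85.2 CPM, and Il18rap, a receptor chain for interleukin-18, was higher at 288 ± 32.8 CPM against 41.8 ± 21.5 CPM. Of 66 ribosomal protein genes 16 were lower (camera adjusted p = 3.47e-22, adjusted p = 0.146 with an estimated correlation), and 41 adjusted over the list alone. Of 30 lysosome and phagocytosis genes 5 were lower (camera adjusted p = 4.02e-10, adjusted p = 0.161 with an estimated correlation), and 18 adjusted over the list alone. Of 15 macrophage marker genes 4 were lower (camera adjusted p = 1.42e-10, adjusted p = 0.11 with an estimated correlation), and 13 adjusted over the list alone. Camera called 23 of 37 lists, 1 higher and 22 lower, and 0 with an estimated correlation. Markers of other cell types moved too: 1 of 9 fibroblast genes was lower, and 1 adjusted over the list alone (camera adjusted p = 0.000817, adjusted p = 0.146 with an estimated correlation), and 1 of 6 erythroid and platelet genes, and 6 adjusted over the list alone (camera adjusted p = 0.00106, adjusted p = 0.146 with an estimated correlation). The lists of endothelium (11 members; camera adjusted p = 0.0122, adjusted p = 0.146 with an estimated correlation) and alveolar epithelium (9 members; camera adjusted p = 0.0399, adjusted p = 0.164 with an estimated correlation) were lower with 0 members called, and 2 and 0 adjusted over the list alone. The NK cell list of 14 was the 1 higher (camera adjusted p = 0.0122, adjusted p = 0.506 with an estimated correlation), yet its 2 called members, Tyrobp and Fcer1g, were lower, as were 2 adjusted over the list alone; both are signalling adaptors that myeloid cells also carry. C1qa, a complement component of macrophages, was 1498 CPM in young 1 and 2.72 to 258 CPM in the other libraries labelled CD25neg young. EdgeR called 175 of 10552 genes, 28 higher and 147 lower, against 547 by DESeq2, 533 in the fit of all 44 libraries and 7 when only these groups were fitted. The count was 5 without aged 1, 16 without aged 2, 565 without young 1, 451 without young 3 and 307 without young 4. Of the 30 named genes called, 5 stayed called without each library in turn (mt-Nd2, mt-Nd1, mt-Cytb, mt-Nd5 and Lyz2). Each of these 5 lay right at the threshold in its weakest fit. Trem2 and Il18rap lost their calls without aged 1 and without aged 2. Either of these fits leaves 1 aged library, whose spread is assumed. The calls of Trem2, Il18rap and mt-Co1 also ended when only these groups were fitted.

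**Figure D3:**
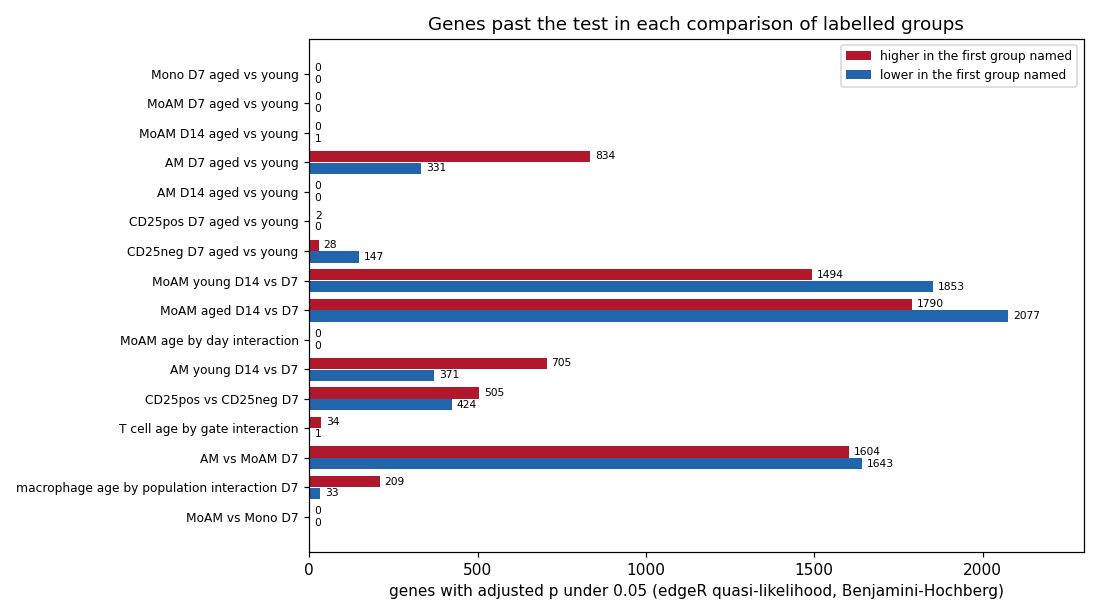
Number of genes past edgeR's test (horizontal axis) in each of the 16 comparisons, split into genes higher and lower in the group named first. Among the comparisons of libraries labelled aged with those labelled young, the counts in these fits are 1165 in AM D7 and 175 in CD25neg.

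For labelled day, the 3 libraries labelled MoAM D14 young were compared with the 4 labelled MoAM D7 young. They differ in lineage lists, taken as mean log2(CPM + 1). The T cell list was 6.33 to 7.24 at D14 and 1.02 to 1.55 at D7. The resident alveolar macrophage list was 3.06 to 4.34 at D14 and 8.38 to 9.01 at D7. The differences between these libraries therefore cannot be read as change with time. Among the genes of T cells higher at D14 were Ikzf4, a zinc finger factor active in regulatory T cells, at least 162-fold at 97.6 ± 23.3 CPM, Slamf1, a costimulatory receptor of lymphocytes, at least 103-fold at 62.4 ± 12.1 CPM, and Il1rl1, the interleukin-33 receptor, at least 68.7-fold at 41.4 ± 13.9 CPM. Among the genes of resident alveolar macrophages lower at D14, Siglecf had 0.927 ± 0.898 CPM against 153 ± 79.8 CPM (log2 fold change -7.47, standard error 0.70, edgeR adjusted p = 4.91e-08) and Car4 28.7 ± 12.9 CPM against 789 ± 102 CPM (log2 fold change -4.72, standard error 0.47, edgeR adjusted p = 2.02e-07). Krt79 was at least 364-fold lower from 135 ± 155 CPM and Fabp1, a fatty acid carrier, at least 221-fold lower from 82.1 ± 63.0 CPM. Ly6c2 was higher (log2 fold change 1.95, standard error 0.54, edgeR adjusted p = 0.0082). All 30 resident alveolar macrophage genes were lower, and all 30 adjusted over the list alone (camera adjusted p = 2.46e-22, adjusted p = 0.0093 with an estimated correlation). Of 16 T cell markers 15 were higher and 15 adjusted over the list alone (camera adjusted p = 4.57e-15, adjusted p = 0.00704 with an estimated correlation). Of 15 T helper genes 10 were higher, and 11 adjusted over the list alone (camera adjusted p = 1.77e-07, adjusted p = 0.0093 with an estimated correlation). Of 30 lysosome and phagocytosis genes 26 were lower, with 29 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.19e-13, adjusted p = 0.167 with an estimated correlation). Markers of other lineages moved with these: 8 of 13 B cell genes were higher and 1 lower, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.157 with an estimated correlation). Of 5 gamma-delta T and innate lymphoid genes 3 were higher, and 3 adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.136 with an estimated correlation). Of 15 macrophage markers 11 were lower and 1 higher, and 13 and 1 adjusted over the list alone (camera adjusted p = 2.91e-06, adjusted p = 0.264 with an estimated correlation). Camera called 18 lists, 10 higher and 8 lower, and 5 with an estimated correlation. EdgeR called 3347 of 10424 genes, 1494 higher and 1853 lower, and 10 of the 18 panel genes, against 5075 genes by limma voom. With RLE size factors 1719 were higher and 1717 lower, so more genes lower than higher depends on the scaling.

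The libraries labelled aged were compared in the same way, 3 labelled MoAM D14 against 4 labelled MoAM D7. Here the T cell list was 6.39 to 6.59 at D14 and 0.515 to 1.58 at D7. This comparison too cannot be read as change with time. Il18r1 was at 188 ± 45.9 CPM against 0.234 ± 0.469 CPM (log2 fold change 9.35, standard error 0.61, edgeR adjusted p = 1.34e-10). Tnfsf11, the ligand RANKL, was at least 58.7-fold higher at 39.1 ± 19.9 CPM, and Cd40lg, the helper signal of activated CD4 T cells, at least 48.9-fold higher at 32.6 ± 9.67 CPM. Ear1, a ribonuclease of alveolar macrophages and eosinophils, was at 1.40 ± 2.27 CPM against 610 ± 291 CPM, and Krt79 was at least 554-fold lower from 157 ± 89.0 CPM. Siglecf and Car4 had log2 fold changes of -4.69 and -5.62 (standard errors 0.55 and 0.49, edgeR adjusted p = 8.71e-07 and 3.16e-08). All 30 resident alveolar macrophage genes were lower, and all 30 adjusted over the list alone (camera adjusted p = 1.06e-19, adjusted p = 0.0192 with an estimated correlation). Of 16 T cell markers 15 were higher and 15 adjusted over the list alone (camera adjusted p = 4.38e-13, adjusted p = 0.0107 with an estimated correlation). For B cells 7 of 13 genes were higher and 1 lower, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.00518, adjusted p = 0.19 with an estimated correlation). Gamma-delta T and innate lymphoid genes were higher in 3 of 5, and 3 adjusted over the list alone (camera adjusted p = 0.00438, adjusted p = 0.0821 with an estimated correlation). Macrophage markers were lower in 12 of 15 and higher in 1, and 13 and 1 adjusted over the list alone (camera adjusted p = 9.3e-06, adjusted p = 0.27 with an estimated correlation). Camera called 18 lists, 9 higher and 9 lower, and 4 with an estimated correlation. EdgeR called 3867 genes, 1790 higher and 2077 lower, and 10 of the 18 panel genes. Under RLE 2014 were higher and 1957 lower, which turns the majority. The test of whether the difference between labelled ages itself differed between days called 0 of 10424 genes by edgeR, with 621 at an unadjusted p under 0.05, against 9 by DESeq2 and 0 by limma voom. Camera called 2 lists with a positive difference, genes encoded by mitochondrial DNA over 8 members and naive and central memory T cell genes over 20 (camera adjusted p = 0.0175 for each, adjusted p = 0.993 with an estimated correlation for each), with 0 members called, and 0 and 1 adjusted over the list alone. Without D14 young 3 the count of genes was 6, without D14 aged 2 it was 5, and without D14 young 1 or D14 aged 1 it was 1.

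The 3 libraries labelled AM D14 young were compared with the 3 labelled AM D7 young. Fn1 was higher at D14 with 4021 ± 1348 CPM against 1065 ± 167.5 CPM (log2 fold change 1.92, standard error 0.35, edgeR adjusted p = 0.00194), and Mmp12 with 1492 ± 861 CPM against 207 ± 61.7 CPM (log2 fold change 2.84, standard error 0.63, edgeR adjusted p = 0.00724). Ly6c2 was at 117 ± 26.6 CPM against 20.8 ± 4.00 CPM and Il1b at 2213 ± 247 CPM against 856 ± 337 CPM. In the fit of all 44 libraries the calls of Mmp12, Fn1 and Il1b ended, and that of Mmp12 ended with no filter too. Tnfsf11 was lower with 0.412 ± 0.463 CPM against 44.1 ± 22.6 CPM (log2 fold change -6.14, standard error 1.18, edgeR adjusted p = 0.00264). Zfp598 was at least 41.6-fold higher at 24.2 ± 7.14 CPM. Of 15 T cell markers 12 were lower, and 14 adjusted over the list alone (camera adjusted p = 3.1e-10, adjusted p = 0.497 with an estimated correlation). Of 15 macrophage markers 9 were higher, and 9 adjusted over the list alone (camera adjusted p = 0.000159, adjusted p = 0.497 with an estimated correlation). Of 45 oxidative phosphorylation genes 27 were higher, and 32 adjusted over the list alone (camera adjusted p = 5.93e-10, adjusted p = 0.497 with an estimated correlation). Ribosomal protein genes were higher in 33 of 66 and lower in 2, and 39 and 4 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.693 with an estimated correlation). Markers of other cell types moved as well: 5 of 8 erythroid and platelet genes were higher, and 6 adjusted over the list alone (camera adjusted p = 0.00116, adjusted p = 0.497 with an estimated correlation). NK cell genes were higher in 3 of 10, and 4 adjusted over the list alone (camera adjusted p = 0.00599, adjusted p = 0.497 with an estimated correlation). Endothelial genes were lower in 3 of 12, and 4 adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.497 with an estimated correlation). Camera called 16 lists, 10 higher and 6 lower, and 0 with an estimated correlation. EdgeR called 1076 of 11682 genes, 705 higher and 371 lower, against 1907 by DESeq2 and 2277 by limma voom. The count was 497 without D14 young 1, 510 without D14 young 2 and 613 without D14 young 3.

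The gate was compared as the 6 libraries labelled CD25pos against the 6 labelled CD25neg, over both labelled ages. Il2ra, the gene of CD25 itself, had 9.77 ± 4.98 CPM against 4.03 ± 7.28 CPM and did not pass (log2 fold change 1.53, standard error 1.18, edgeR adjusted p = 0.467). Of the 11 T cell panel genes tested 4 were called. Il1rl1 and the proliferation marker Mki67 were higher (log2 fold changes 3.96 and 1.88, standard errors 1.08 and 0.55, edgeR adjusted p = 0.0333 and 0.0455). Gata3, the transcription factor of type 2 helper T cells, and Ifng, the cytokine interferon gamma, were lower (log2 fold changes -3.21 and -6.01, standard errors 0.83 and 1.55, edgeR adjusted p = 0.025 and 0.0294). Each of these 4 calls ended without any 1 of the 6 libraries labelled CD25pos and without CD25neg aged 2, and those of Mki67, Gata3 and Ifng without CD25neg aged 1. Their highest edgeR adjusted p were 0.135, 0.247, 0.104 and 0.0945 for Il1rl1, Mki67, Gata3 and Ifng, and the Mki67 call also ended with the replicate number as a block. Lower in CD25pos were Nkg7, a protein of cytotoxic granules, with 1.60 ± 2.10 CPM against 117.5 ± 129 CPM (log2 fold change -6.15, standard error 1.02, edgeR adjusted p = 0.00366), and Ccl5, a chemokine of T and NK cells, with 65.8 ± 10.7 CPM against 819.5 ± 674 CPM (log2 fold change -3.70, standard error 0.63, edgeR adjusted p = 0.0063). Gimap6, a GTPase of lymphocyte survival, was at 13.9 ± 3.05 CPM against 94.4 ± 51.9 CPM. Of 30 lysosome and phagocytosis genes 19 were higher, and 27 adjusted over the list alone (camera adjusted p = 1.9e-15, adjusted p = 0.142 with an estimated correlation). Of 15 macrophage markers 11 were higher, and 15 adjusted over the list alone (camera adjusted p = 1.28e-08, adjusted p = 0.142 with an estimated correlation). Of 14 NK cell genes 10 were lower and 2 higher, and 12 and 2 adjusted over the list alone (camera adjusted p = 7.37e-07, adjusted p = 0.213 with an estimated correlation). The 2 higher were Tyrobp and Fcer1g, signalling adaptors that myeloid cells also carry. Of 12 T cell markers 1 was lower and 0 higher, and 1 adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.213 with an estimated correlation). Dendritic cell genes were higher in 2 of 14, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00685, adjusted p = 0.213 with an estimated correlation). Camera called 21 lists, 16 higher and 5 lower, and 0 with an estimated correlation. EdgeR called 929 of 10552 genes, 505 higher and 424 lower, against 1522 by DESeq2, 2500 by limma voom and 1780 in the fit of all 44 libraries. Without 1 library the count was 164 for CD25neg aged 1, 245 for CD25neg aged 2, 2063 for CD25neg young 1 and 1535 for CD25neg young 4, and for CD25pos 396, 426 and 490 for young 1, 2 and 3 and 379, 487 and 548 for aged 1, 2 and 3. Of the 14 named genes called, Nkg7, Ccl5 and Gimap6 stayed called each time.

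The difference between labelled ages was tested for a difference between the gates labelled CD25pos and CD25neg. Kcnmb2 (log2 difference 3.61, standard error 0.47) and mt-Nd2 (log2 difference 3.49, standard error 0.40) had a more positive change from young to aged in CD25pos than in CD25neg, each with an edgeR adjusted p of 0.00196. The Kcnmb2 call ended in the fit of all 44 libraries. Of 7 genes encoded by mitochondrial DNA 6 passed in that direction, and 6 adjusted over the list alone (camera adjusted p = 5.34e-14, adjusted p = 0.0545 with an estimated correlation). Of 66 ribosomal protein genes 9 passed, and 46 adjusted over the list alone (camera adjusted p = 1.23e-33, adjusted p = 0.146 with an estimated correlation). Macrophage markers passed in 1 of 15, and 10 adjusted over the list alone (camera adjusted p = 1.38e-09, adjusted p = 0.146 with an estimated correlation). Erythroid and platelet genes passed in 0 of 6, and 2 adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.258 with an estimated correlation). The NK cell list had a negative difference over 14 members (camera adjusted p = 0.0475, adjusted p = 0.643 with an estimated correlation), with 0 called and 2 positive adjusted over the list alone, Tyrobp and Fcer1g. Camera called 14 lists, 13 positive and 1 negative, and 0 with an estimated correlation. EdgeR called 35 of 10552 genes, 34 with a positive and 1 with a negative difference, against 204 by DESeq2, 204 by limma voom, 53 with RLE size factors, 208 with no filter and 84 in the fit of all 44 libraries. Without 1 library the count was 2 for CD25neg aged 1, 13 for CD25neg aged 2, and 66, 64, 142 and 80 for CD25neg young 1, 2, 3 and 4. For CD25pos it was 7, 8 and 10 without young 1, 2 and 3 and 7, 8 and 13 without aged 1, 2 and 3. Of the 6 named genes called, 2 stayed called without each library in turn, Kcnmb2 and mt-Nd2.

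The 7 libraries labelled AM D7 were compared with the 8 labelled MoAM D7, over both labelled ages. Lower in those labelled AM were Car4 with 108 ± 47.4 CPM against 873 ± 179 CPM (log2 fold change -3.01, standard error 0.20, edgeR adjusted p = 3.83e-11), Fabp4 with 38.7 ± 17.8 CPM against 367 ± 220 CPM (log2 fold change -3.17, standard error 0.26, edgeR adjusted p = 1.19e-09) and Marco with 1.17 ± 1.64 CPM against 167 ± 145 CPM (log2 fold change -6.96, standard error 1.36, edgeR adjusted p = 0.00204). Higher were Il1rl1 with 115 ± 108 CPM against 0.0440 ± 0.124 CPM, Cd6, a costimulatory receptor of T cells, with 80.6 ± 44.9 CPM against 0.501 ± 1.16 CPM, and Ccr6, a chemokine receptor of lymphocytes, with 26.1 ± 10.9 CPM against 0.782 ± 1.34 CPM. Of 30 resident alveolar macrophage genes 29 were lower, and 29 adjusted over the list alone (camera adjusted p = 5.52e-23, adjusted p = 0.0258 with an estimated correlation). Of 15 T cell markers 14 were higher, and 14 adjusted over the list alone (camera adjusted p = 8.54e-12, adjusted p = 0.106 with an estimated correlation). The library labelled AM D7 aged 4 stood apart, with a mean log2(CPM + 1) of 2.48 in the T cell list against 5.01 to 6.5 in the others labelled AM D7. Of 45 oxidative phosphorylation genes 36 were lower, and 39 adjusted over the list alone (camera adjusted p = 1.97e-11, adjusted p = 0.108 with an estimated correlation). Macrophage markers were lower in 11 of 15 and higher in 1, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.000391, adjusted p = 0.156 with an estimated correlation). Other cell types had markers higher: 9 of 16 dendritic cell genes, with 2 lower, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.000582, adjusted p = 0.106 with an estimated correlation), and 3 of 5 gamma-delta T and innate lymphoid genes, and 3 adjusted over the list alone (camera adjusted p = 0.000632, adjusted p = 0.084 with an estimated correlation). Endothelial genes were higher in 7 of 11 and lower in 1, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.004, adjusted p = 0.299 with an estimated correlation). Neutrophil genes were higher in 9 of 14 and lower in 2, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.411 with an estimated correlation). B cell genes were higher in 4 of 11 and lower in 1, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.347 with an estimated correlation). Camera called 26 lists, 18 higher and 8 lower, and 1 with an estimated correlation. EdgeR called 3247 of 10737 genes, 1604 higher and 1643 lower, and 10 of the 18 panel genes. Of the 19 named genes called, 18 stayed called without each library in turn. The Marco call ended by limma voom.

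Whether the difference between labelled ages differed between AM and MoAM at D7 was tested in the same 15 libraries. Zfp598 (log2 difference 7.97, standard error 1.51, edgeR adjusted p = 0.00469) and Mlst8, a subunit of the mTOR kinase complexes (log2 difference 8.61, standard error 1.75, edgeR adjusted p = 0.0076), had a more positive change from young to aged in the libraries labelled AM. Rufy4, a regulator of autophagy, had the opposite direction (log2 difference -4.72, standard error 1.05, edgeR adjusted p = 0.0141). Of 66 ribosomal protein genes 25 passed with a positive difference, and 39 with 1 negative adjusted over the list alone (camera adjusted p = 3.73e-10, adjusted p = 0.914 with an estimated correlation). Of 45 oxidative phosphorylation genes 13 passed, and 21 adjusted over the list alone (camera adjusted p = 7.59e-10, adjusted p = 0.591 with an estimated correlation). Erythroid and platelet genes passed in 4 of 6, and 4 adjusted over the list alone (camera adjusted p = 6e-05, adjusted p = 0.354 with an estimated correlation), and NK cell genes in 1 of 6, and 4 adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.239 with an estimated correlation). Camera called 8 lists, all 8 with a positive difference, and 0 with an estimated correlation. EdgeR called 242 of 10737 genes, 209 positive and 33 negative, and none of the 18 panel genes, against 484 by DESeq2. Without 1 library labelled MoAM the count was 150 for young 1, 155 for young 4, 151 for aged 2, 132 for aged 3 and 157 for aged 4. Of the 10 named genes called, 4 stayed called without each library in turn, among them Zfp598, Mlst8 and Rufy4.

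The 8 libraries labelled MoAM D7 and the 5 labelled monocytes D7 both held genes of resident alveolar macrophages. Car4 had 820 ± 169 CPM against 733 ± 195 CPM, Pparg, the nuclear receptor that sets alveolar macrophage identity, 165 ± 36.3 CPM against 164 ± 25.97 CPM, and Ly6c2 20.6 ± 15.6 CPM against 18.8 ± 16.2 CPM. EdgeR called 0 of 9115 genes, with 314 at an unadjusted p under 0.05, against 0 by DESeq2 and by limma voom, and 3 without MoAM aged 1. The resident alveolar macrophage list was higher in MoAM over 30 members and the MHC class II list lower over 8 (camera adjusted p = 0.00213 for each, adjusted p = 0.678 with an estimated correlation for each), with 0 members called over all genes and 0 adjusted over the list alone. A miss of the threshold does not show that the levels were equal.

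The last comparison asked whether libraries labelled MoAM D14 aged lay nearer to AM than those labelled young, through genes that differed between young AM and MoAM at D7. The list of 100 genes lower in AM was higher in aged (camera adjusted p = 0.0137, adjusted p = 0.413 with an estimated correlation) and the list of 100 genes higher in AM did not pass (camera adjusted p = 0.356). The call ended without young 1 (camera adjusted p = 0.0823) and without aged 3 (camera adjusted p = 0.201), and with lists of 50 genes (camera adjusted p = 0.117) or 200 (camera adjusted p = 0.105). These lists were chosen on libraries of this study, and both populations carry labels that lineage genes go against, so their direction is no independent evidence on macrophage identity.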

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

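The 14 measures compared between single libraries were chosen only after the lineage genes had been seen; the interaction tests and the splits were set before. Single libraries were compared with the rest of their group for 14 measures in the 4 groups of 4 libraries, and 12 of 56 tests placed a library far from the others, where chance alone places about 1 in 20. That rate does not hold for genes near 0, since any count beside 3 libraries at 0 gives the largest value of the measure, so the 12 cannot be set against chance. For MoAM D7 young, Cd4 was 2.83 CPM in young 3 and 0 in the others, and Lyz2 was 36964 CPM in young 3 and 39565 to 40025 CPM in the others. In those labelled MoAM D7 aged, Cd3e was 2.57 CPM in aged 1 and 0 in the others, and Foxp3 was 8.2 CPM in aged 2 and 0 to 0.642 CPM in the others. Spp1 was 11215 CPM in MoAM D7 aged 1 against 985 to 1627 CPM. Among the libraries labelled AM D7 aged, Foxp3 was 1.74 CPM in aged 4 against 96.7 to 114 CPM, and Spp1 was 6638 CPM in aged 4 against 1592 to 1813 CPM. Among those labelled CD25neg young, Cd3e was 29 CPM in young 2 against 0 to 2.55 CPM and Marco was 6.35 CPM in young 2 against 0 to 0.823 CPM. C1qa was 1498 CPM in CD25neg young 1 against 2.72 to 258 CPM, Siglecf 16.6 CPM against 0 to 0.823 CPM and Cd4 7.66 CPM against 0.

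The difference between labelled ages itself differed between groups in 35 genes for CD25pos against CD25neg, by the interaction term in edgeR. For AM against MoAM at D7 it differed in 242 genes by that test. Of 100 splits drawn for the latter comparison, the real one included, 2 gave as many genes, a share under 0.05. The other of these gave 465, more than the real 242. A count of this size can thus come from another grouping of the same libraries, so chance is not excluded. No split was counted for the former, since the libraries labelled CD25neg aged number 2.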

How the results depend on the processing

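The alternatives were all chosen before the data were examined. Over them, named genes kept their direction and side of the threshold in 6056 values, lost the call in 356 and gained it in 132, with 0 reversed; a gene uncalled throughout counts as kept whatever its sign. Counts of calls stayed within 1.5 times the reported count in 173 values and moved further in 91. Lists kept their call in 875 values, lost it in 278, gained it in 28 and reversed in 1, the eosinophil and basophil list in AM against MoAM D7 (0.0435 by fry); all 200 called lists kept their direction under RLE, 199 of them called. RLE moved the median log2 fold change of D14 against D7 from -0.0465 to 0.0587 for MoAM young and from -0.0403 to 0.0418 for MoAM aged, and turned its sign also for age by gate (-0.0367 to 0.0358), AM D14 (-0.0304 to 0.0198), monocytes (-0.00232 to 0.00492) and MoAM against monocytes (0.0103 to -0.00482). Except where stated, the cause was not tested. At this depth and group size the aged against young comparisons recovered 2 to 20 of 100 simulated 2-fold changes. Without 1 of the 2 libraries labelled monocytes young or CD25neg aged, the remaining one is assumed to vary like the other groups.

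With DESeq2 the counts were 2198 for AM D7, 1907 for AM young by day, 484 for age by macrophage population, 27 for MoAM D14, 9 for MoAM age by day, 204 for age by CD25 gate, 11 for CD25pos, 547 for CD25neg and 1522 for the gate. With limma voom they were 1277 for AM D14, 2277 for AM young by day, 2 for MoAM D14, 9 for MoAM D7, 5075 for MoAM young by day, 204 for age by gate, 545 for CD25pos and 2500 for the gate. With no filter they were 16 for MoAM D14, 10 for MoAM age by day, 3 for MoAM against monocytes, 13 for monocytes, 208 for age by gate, 16 for CD25pos and 454 for CD25neg, and with RLE 53 for age by gate. With all 44 libraries in one fit they were 3 for MoAM D14, 84 for age by gate, 1 for CD25pos, 533 for CD25neg and 1780 for the gate. With only the groups compared they were 216 for AM D7, 84 for AM D14, 0 for MoAM D14, 695 for CD25pos and 7 for CD25neg, where fewer libraries estimate the spread. The list lower in AM had camera adjusted p of 0.117 with 50 genes, 0.105 with 200 and 0.413 with an estimated correlation.

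Replicate numbers gave no sign of pairing: same-numbered deviations correlated from -0.139 to 0.0876 within the fits, and in MoAM against monocytes 1 of 16 pairs, at 0.2, was over 0.1. The numbers belong to the labels that lineage genes go against, so a pairing of the values cannot be excluded. With the replicate number as a block the counts were 143 for age by macrophage population, 0 for MoAM D14 and 2 for monocytes, and the other counts stayed within 1.5 times.

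Without each library in turn, counts ran from 0 to 140 for monocytes, 0 to 0 for MoAM D7, 1 to 80 for MoAM D14, 870 to 1612 for AM D7, 0 to 3 for AM D14, 1 to 1 for CD25pos, 5 to 565 for CD25neg, 2791 to 3138 for MoAM young by day, 3286 to 3791 for MoAM aged by day, 0 to 6 for MoAM age by day, 497 to 1253 for AM young by day, 164 to 2063 for the gate, 2 to 142 for age by gate, 2855 to 3633 for AM against MoAM, 132 to 347 for age by macrophage population and 0 to 3 for MoAM against monocytes. The highest or lowest came without aged 1 for monocytes (140), D14 young 3 for MoAM D14 (80) and MoAM age by day (6), young 3 for AM D14 (3), D14 young 1 for AM young by day (497), CD25neg aged 1 for CD25neg (5), the gate (164) and age by gate (2), CD25neg young 1 for CD25neg (565) and the gate (2063), CD25neg young 3 for age by gate (142), MoAM aged 3 for age by macrophage population (132) and MoAM aged 1 for MoAM against monocytes (3). The list lower in AM ran from 0.00439 to 0.201 and the list higher in AM from 0.0879 to 0.893 (camera adjusted p). Named genes called both in the reported fit and without each library numbered 22 of 34 for AM D7, 5 of 30 for CD25neg, 14 of 19 for MoAM young by day, 16 of 20 for MoAM aged by day, 9 of 15 for AM young by day, 3 of 14 for the gate, 18 of 19 for AM against MoAM, 4 of 10 for age by macrophage population, 2 of 6 for age by gate, 1 of 2 for CD25pos and 0 of 1 for MoAM D14; the other comparisons had 0 called.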

Other observations

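Further lists fixed beforehand passed in the comparison of the libraries labelled AM D7 with those labelled MoAM D7. Of 29 genes for inflammatory cytokines and chemokines, which draw and activate leukocytes, 19 were higher and 2 lower, with 20 and 2 adjusted over the list alone (camera adjusted p = 2.31e-05, adjusted p = 0.106 with an estimated correlation). Of 24 regulatory T cell identity genes, 19 were higher and 2 lower, and likewise 19 and 2 adjusted over the list alone (camera adjusted p = 1.74e-08, adjusted p = 0.084 with an estimated correlation). Of 22 cholesterol biosynthesis genes 11 were lower, and 15 adjusted over the list alone (camera adjusted p = 5.75e-06, adjusted p = 0.084 with an estimated correlation). In the libraries labelled CD25pos, 8 of 11 MHC class II genes were higher than in those labelled CD25neg, and 8 adjusted over the list alone (camera adjusted p = 6.05e-06, adjusted p = 0.213 with an estimated correlation).

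Chosen only after the results were seen were the tests of the order of the column names, of macrophages in T cell sorts, of marrow age, and of the library labelled AM D7 aged 4; the thinning of depth and the splits were chosen before. For the lineage genes that go against the labels, macrophage RNA carried into correctly labelled T cell sorts is argued against as the whole cause. It brings no T cell transcripts to other libraries, and the 12 highest in the T cell list were 6 labelled MoAM D14, 6 labelled AM D7 and 0 of the 12 labelled CD25pos or CD25neg. Marrow age is argued against as the whole cause, since it leaves the libraries labelled young in place and 0 of the 7 labelled CD25pos or CD25neg young were among them. Both counts had been seen before and restate the pattern. They argue against these only as the whole cause and support no other cause. A candidate explanation is that the column names stand in another order than the values: with the names sorted as text over the values as they stand, 30 of 30 libraries were among the highest of their own lineage list, against 0 of 30 as labelled and at most 16 of 30 in 1000 random orders. With sorted names the common biological coefficient of variation over the 14 groups was 0.466, against 0.538 as labelled and 0.674 to 0.755 in 20 random orders, and the nearest library had the same group for 27 of 44 libraries, against 20 of 44 as labelled and 0 to 9 in 1000 random orders. This order was found on the same data and stays a hypothesis, so no library was moved between groups and no comparison was made under it.

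For the 1165 genes called between the libraries labelled AM D7 aged and young, depth was tested by thinning every library labelled AM to 234968 counts, which left 884 calls. Of the called genes 855 were still tested, with a median ratio of thinned to full log2 fold change of 0.992 (quartiles 0.878 and 1.12), all 855 of the same sign. Their differences thus remained at equal totals. Thinning draws from the same counts and keeps the expected share of each gene, so a ratio near 1 was likely whatever the cause. It therefore does not decide on depth for these genes. The other 310 passed the filter no more. Fitted with the counts left, their median ratio was 0.867 (quartiles 0.613 and 1.13), at a median of 4.75 counts in the higher group, too few to decide. For these 310 depth stays open too. Without the library labelled AM D7 aged 4, low in T cell genes, 1612 genes were called. The rise in the count decides nothing, since leaving out a library that stands apart can lower the spread. Of the 1165 genes, 1087 were still called, which argues against that library as the source of these 1087 calls. The rest were not called without it, among them Fn1 and Mmp12. Of 35 splits of these 7 libraries, only the real one (1) gave as many calls, a share under 0.05. The highest other split gave 549. With 35 splits the share cannot fall below 1 of 35, and it was not adjusted for the number of comparisons. Chance is thus unlikely as the source of the count but not excluded. Marrow age may be the cause but cannot be told apart from other differences, since 0 of the 7 libraries labelled AM D7 were among the highest in the resident alveolar macrophage list and the ages behind the values stay open.

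For the other counts, splits of the same libraries were compared with the real one. Only the real split gave as many calls in 4 comparisons. These were MoAM young by day (3347 genes, 1 of 35 splits, highest other 768) and MoAM aged by day (3867, 1 of 35, 779). The others were the CD25 gate (929, 1 of 100, 689) and AM against MoAM (3247, 1 of 100, 164). Each share is under 0.05 but was not adjusted for the number of comparisons, so chance is unlikely and not excluded. With a real count of 0 every split gives as many, so the splits say nothing about chance for MoAM D7 aged against young (0 genes; 35 of 35, highest other 15), age by day in MoAM (0; 100 of 100, 16) and MoAM against monocytes (0; 100 of 100, 451). What sets apart the sides of the MoAM against monocytes split with 451 calls was not tested. With 10 splits, too few for a share under 0.05, the real and highest other counts were 1 and 121 for MoAM D14, with 5 splits as large, 0 and 0 for AM D14, with 10, 2 and 0 for CD25pos, with 1, and 1076 and 0 for AM young by day, with 1. The MoAM D14 split with 121 calls sets young 3, aged 1 and aged 2 against the rest. In the classical monocyte list young 3 and aged 1 scored 4.81 and 4.51. Aged 2, on their side, scored 6.18, near the 6.46 to 6.52 of young 1, young 2 and aged 3, so the list does not follow the split. Whether the low scores of young 3 and aged 1 made the 121 calls was not tested. For the list lower in AM tested in MoAM D14 the 10 splits are likewise too few, with a real camera p of 0.00684, a smallest other p of 0.0267 and 1 split as small.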
